A study of Caenorhabditis elegans with 12 samples.

How the data were processed

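Wild-type N2 (Bristol) Caenorhabditis elegans were age-synchronised by bleaching, and larvae 12 h old were placed for 48 h in control solution or in 1 of 3 silver solutions, per the labels' protocols. Each silver solution was set at the concentration with a 30% effect on reproduction, per the labels' protocols, so the 3 exposures were matched on that effect and not on dose. The concentrations themselves are not analysed here. The exposures were sulfidized (aged) silver nanoparticles, pristine silver nanoparticles and silver nitrate, per the labels. RNA came from populations of 2000 to 3000 animals at 1 time point, per the study's design note. Total RNA was extracted with Trizol and 100 ng was labelled with biotin using the Affymetrix IVT Express kit, per the labels' protocols. There were 4 groups of 3 arrays, 12 in all. The probe annotation names the Affymetrix C. elegans Genome Array. The labels do not say whether the replicates of a group were separate cultures, so every p-value measures only the spread between samples, which may be technical.

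The deposited values were an intensity for each of 22625 probe sets on a linear scale. They were never negative, array medians lay between 119.1 and 135.1, and maxima lay between 25316 and 38126. The mean after trimming 2% from each end lay between 500.1 and 500.2 in every array, so the deposited intensity values had already been scaled between arrays. The summarisation method and the software were not given in the sources used here, and detection calls were not used here.

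Array controls (77 probe sets) were set aside, which left 22548 probe sets for testing. Of these, 20766 carried 1 gene each and stood for 17118 genes, 887 carried several genes, and 895 carried no gene name. Names came from the reference gene table for 20701 probe sets, and 65 kept the platform's name. Probe sets with several genes or none stayed in the tests and are not named. For gene groups, the probe set with the highest mean over all 12 arrays stood for a gene with more than 1 (2981 genes). Those further probe sets stayed in the counts, and 8 genes had probe sets that moved in opposite directions at an unadjusted p under 0.05.

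Each array was scaled to the common median and values under a signal of 16 were set to 16 (4 on the log2 scale) before taking log2. Between 13.7% and 15.8% of probe sets lay under this floor in an array, and 744 lay at it in all arrays. Where 1 or more arrays of the lower group lay at the floor, the fold is a lower bound and is given as "at least", and a log2 difference from such a group is a lower bound in size. The median scaling moved the exposed groups against control by −0.03 (aged), −0.03 (pristine) and −0.07 (silver nitrate) on the log2 scale. All 12 arrays entered 1 limma model with a mean per group (8 residual degrees of freedom, 0.94 prior degrees of freedom). A group wholly at the floor has no spread, which lowers the spread that the model pools over the groups. The 6 pairwise contrasts and the F test over the 3 exposures were each adjusted by Benjamini-Hochberg over all 22548 probe sets, and a probe set was called changed at an adjusted p under 0.05. The adjusted p-values of probe sets in every part of the text are from limma.

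Gene groups were tested with camera of the limma package, which compares a group with all other genes, with its preset correlation of 0.01. There were 38 gene lists and 165 gene classes with at least 10 measured genes, a class being the letters of a symbol before the hyphen. Adjustment was over the lists, or the classes, within a contrast. The preset correlation ignores how strongly genes of a group move together, so the adjusted p with an estimated correlation is given beside each list. With the estimated correlation, 2 of the 53 list calls held, those of the collagens between the aged-particle group and each other exposure. The fry test, which asks whether a list's genes move one way on balance and compares it with no other gene, called 9. No called list had a median, mean and test that differed in sign. List members are counted past the threshold over all probe sets, and also adjusted over the list alone.

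RNA integrity was read as the 3-prime minus 5-prime log2 signal of 3 array control genes, with a two-sided exact permutation test per exposure. The groups, lists, comparisons, this permutation test and the rule for named genes were chosen before the data were examined. The tests of RNA integrity and of the neuron marker share as explanations, and the 2 settings given last among the alternatives, were chosen after the results were seen. Named for an exposure against control were the 12 genes with the highest and the 12 with the lowest log2 change among called genes whose arrays did not overlap. Between exposures it was 6 each way, and in a list the 4 members with the smallest p against control. Where fewer than 5 genes were called, the 5 with the smallest p were taken as values. Some genes that the rule allows are left out for room. The genes mtl-1, mtl-2, numr-1, cdr-1, hsp-16.2, hsp-4, gst-4, sod-3, vit-2 and vit-6 were to be named whatever their values. The numr-1 gene shares its probe set with another gene and is not named by itself. Any other gene is said to have been chosen after its values were seen.

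On simulated data for the aged-particle comparison, with 200 changed genes drawn from those above median brightness, the limma step over 22548 probe sets recovered 73.2% of genes changed 2-fold and 98% of those changed 4-fold, with a mean of 16.2 false calls among 187.4. Over the 11274 probe sets above median brightness it recovered 84.8% and 92.8%, with a mean of 11.6 false calls among 189.2. The simulated probe sets varied independently. With 200 planted changes, the p needed to pass was looser than where few probe sets change. These shares thus do not give the recovery in the real comparison, where 2 probe sets were called. A simulated list shift of 0.3 was called by camera in 20 of 20 runs with genes that varied independently, and no list was called for pristine particles against control, where nothing was shifted.

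Alternatives were quantile normalisation, centring on array medians, limma with an intensity trend and robust fit, array weights, the replicate number as a block, floors of 1 and 64, filters on dim probe sets, fits with the 6 compared arrays alone, fold and stricter thresholds, averaging of a gene's probe sets, and leaving out each array in turn. The deposited scaling without median scaling, and gene lists over probe sets above median brightness, were added after the data were seen. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The number of arrays limits the precision.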

Results

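Gene expression was measured in whole Caenorhabditis elegans after 48 h in control solution, sulfidized (aged) silver nanoparticles, pristine silver nanoparticles or silver nitrate, with 3 arrays per group. Each silver form was given at the concentration with a 30% effect on reproduction. The question, as the study's title and labels give it, was which genes respond to sulfidized particles and how this compares with unaltered particles and with the salt. Array medians lay between 119.1 and 135.1 signal units and maxima between 25316 and 38126. Pairs of arrays correlated across probe sets at r = 0.974 to 0.982 within groups and 0.968 to 0.983 between groups, and probe sets are not independent replicates. No pair shared more than 1 identical value.

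In animals exposed to aged particles, cuticle collagen genes rose as a group against control. Of 145 measured collagens, 112 lay higher, with a median log2 difference of 0.36 (camera adjusted p = 1.1e-16, adjusted p = 0.0818 with an estimated correlation). The collagen col-164 rose at least 7.96-fold, from a log2 signal of 4.19 ± 0.33 in control, where 2 of 3 arrays lay at the floor, to 7.18 ± 0.25 (SD, n = 3 arrays each; limma adjusted p = 0.000452). That p rests on a spread pooled over all groups. In all pristine and silver nitrate arrays col-164 lay at the floor, with an SD of 0, which lowers this spread. The call ended with the 6 compared arrays alone. This gene was the 1 collagen that rose over all probe sets, and 19 rose adjusted over the list alone. Body wall muscle markers rose too, with 15 of 19 genes higher and a median of 0.31 (adjusted p = 5.42e-05, adjusted p = 0.411 with an estimated correlation). None of the 19 passed by itself, among them mup-4, which codes for an epidermal membrane protein that anchors muscle to the cuticle (1.05), and the muscle gene dim-1 (0.49). The muscle median was 0.48 without control replicate 1 and 0.17 without control replicate 2.

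Genes of the molting cycle, 32 measured, rose in aged-particle animals with a median of 0.33 (adjusted p = 0.00078, adjusted p = 0.347 with an estimated correlation). The median was 0.14 over probe sets above median brightness. No member passed over all probe sets and 1 did adjusted over the list alone. Members with the smallest p were bli-5, whose loss blisters the cuticle (1.27, adjusted p = 0.11, control at the floor), and the protease inhibitor mlt-11 (1.39, adjusted p = 0.44). Lysozymes and antimicrobial effectors, 70 measured, rose with a median of 0.08 (adjusted p = 0.00325, adjusted p = 0.347 with an estimated correlation). None passed over all probe sets and 5 did adjusted over the list alone. Values for caenacins, a family of antimicrobial peptides, were 1.08 for cnc-1 (adjusted p = 0.159) and 1.63 for cnc-5 (adjusted p = 0.195). Without aged replicate 2 the median of this list was 0.01 and the call ended (adjusted p = 0.0739), and the median was 0.14 without control replicate 2 and 0.13 after quantile normalisation. Neuropeptide genes fell, with 54 of 72 lower and a median of −0.13 (adjusted p = 0.00126, adjusted p = 0.612 with an estimated correlation). That call ended without control replicate 2 (median −0.04, adjusted p = 0.429), and the median was −0.07 after quantile normalisation. The neuron markers did not pass (median −0.10, adjusted p = 0.452).

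Over all probe sets, limma called 2 changed between aged particles and control, 1 higher and 1 lower, and 1860 had an unadjusted p under 0.05 where chance gives 1127. The lower one was 1 of 3 probe sets of lem-4, which codes for a LEM-domain protein of the nuclear envelope and was chosen after its values were seen (log2 difference −1.08 ± 0.07 SE, adjusted p = 0.00122). It lay near the floor in control (5.17), with 1 aged-particle array at it, and the brightest lem-4 probe set differed by 0.21. Genes next in order of p were bli-5 (1.27, adjusted p = 0.11), fnip-2 (−0.86, adjusted p = 0.11), nol-53 (−0.89, adjusted p = 0.11) and cnc-1 (1.08, adjusted p = 0.159). Among the 11274 probe sets above median brightness, 13 were called (9 higher, 4 lower), and without the dimmest 25% 0 were (limma, 1416 with an unadjusted p under 0.05). The count was 7, 16 and 8 without control replicates 1, 2 and 3, then 8, 4 and 6 without aged replicates 1, 2 and 3, and 6 without pristine replicate 1. Both probe sets called with all 12 arrays, of col-164 and lem-4, stayed called in each of these leave-one-out fits. Neither was called with the 6 compared arrays alone (adjusted p = 0.148 for col-164 and 0.173 for lem-4), where 1 other probe set was, and both were too dim for either brightness filter. Both lay at the floor in all pristine and silver nitrate arrays, which lowers the spread pooled over all 12 arrays. The lem-4 call also ended with a trend and robust fit (adjusted p = 0.0649) and with floors of 1 and 64 (0.657 and 1).

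In pristine-particle animals, genes of germline proliferation and meiosis rose and neuropeptide genes fell against control. Of 35 germline genes, 30 lay higher, with a median of 0.29 (adjusted p = 1.25e-05, adjusted p = 0.319 with an estimated correlation). None passed by itself, and members with the smallest p included the P granule helicases glh-1 (0.77, adjusted p = 0.409) and glh-2 (0.73, adjusted p = 0.256). The mean level of the germline list, less that of control, was 0.26 to 0.38 on the pristine arrays and 0.28 on control replicate 1, against −0.14 on each other control array. Of 72 neuropeptide genes, 55 lay lower, with a median of −0.17 (adjusted p = 2.24e-07, adjusted p = 0.436 with an estimated correlation). None passed over all probe sets, while 14 fell and 1 rose adjusted over the list alone. Examples were the insulin-like ins-4 (−0.76, adjusted p = 0.0944), nlp-20 (−0.72, adjusted p = 0.131) and nlp-21 (−0.53, adjusted p = 0.103). The neuropeptide median was −0.06 without control replicate 2 and −0.11 after quantile normalisation. The 30 neuron markers did not pass in this contrast (median −0.01, adjusted p = 0.624).

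UDP-glucuronosyltransferases, enzymes that conjugate foreign compounds, rose in pristine-particle animals, with 46 of 64 higher and a median of 0.13 (adjusted p = 0.00504, adjusted p = 0.319 with an estimated correlation). None passed over all probe sets, and 1 rose and 1 fell adjusted over the list alone. The value for ugt-17 was 0.90 (adjusted p = 0.227). Oocyte and eggshell genes rose as a group, with 24 of 30 lying higher and a median of 0.23 (adjusted p = 0.00491, adjusted p = 0.425 with an estimated correlation). Over all probe sets none passed, 1 rose adjusted over the list alone, and the value for cpg-2, an eggshell proteoglycan, was 0.78 (adjusted p = 0.197). Collagens fell as a group, with 99 of 145 lying lower and a median of −0.19 (adjusted p = 0.0012, adjusted p = 0.425 with an estimated correlation), and 2 fell adjusted over the list alone. The glucuronosyltransferase call ended without control replicate 1 (median 0.18, adjusted p = 0.0775), the oocyte call without control replicate 2 (0.13, 0.16) and the collagen call without control replicate 3 (−0.11, 0.0695). The oocyte median was 0.36 without control replicate 1 and 0.13 without pristine replicate 1.

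For pristine particles against control, limma called 1 probe set, and 1945 had an unadjusted p under 0.05. It was the same lem-4 probe set as for the aged particles, at the floor in all 3 pristine arrays and so at least 2.25-fold lower (adjusted p = 0.00123); the brightest lem-4 probe set differed by 0.20. Genes next in order of p did not pass. They were the collagen col-114 (−2.61, adjusted p = 0.064), the lysozyme ilys-3 (−1.35, adjusted p = 0.064), idpp-13 (1.20, adjusted p = 0.064, control at the floor), sst-20 (1.99, adjusted p = 0.0655, 2 of 3 control arrays at the floor) and ctdh-1 (−0.68, adjusted p = 0.0655). Above median brightness 13 probe sets were called (3 higher, 10 lower), after quantile normalisation 19 were (6 higher, 13 lower), and with the 6 compared arrays alone 0 were (limma, 1782 with an unadjusted p under 0.05). The count was 17, 11 and 6 without control replicates 1, 2 and 3, then 8, 6 and 3 without pristine replicates 1, 2 and 3, 2 without aged replicate 1 and 4 without silver nitrate replicate 2.

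With silver nitrate, several cuticle collagen genes and the ground-like genes grl-20 and grl-23, which are related to hedgehog, fell by large factors. The gene grl-20 was at least 45.5-fold lower, from 9.51 ± 0.83 in control to the floor in all 3 silver nitrate arrays (SD; adjusted p = 0.0155). Its other probe set, over the floor in every array but near it with silver nitrate (mean 4.99), was 13.7-fold lower (adjusted p = 0.0477). The related grl-23, at the floor in 2 silver nitrate arrays, was at least 28.1-fold lower (adjusted p = 0.0188). The collagens col-37 and col-158 were at least 21-fold and 18.4-fold lower (adjusted p = 0.0257 and 0.0104), and col-84 and col-114, each at the floor in 1 silver nitrate array, were at least 7.93-fold and 6.9-fold lower (adjusted p = 0.0454 and 0.0257). The invertebrate-type lysozyme ilys-3 fell 3.46-fold (adjusted p = 0.0104) and the astacin protease nas-39 fell 2.33-fold (adjusted p = 0.0257). Collagens fell as a group, with 101 of 145 lying lower and a median of −0.21 (adjusted p = 8.57e-05, adjusted p = 0.292 with an estimated correlation). Of the 145, 4 fell over all probe sets and 15 adjusted over the list alone. The 32 molting-cycle genes had a median of 0.02 and did not pass (adjusted p = 0.983). Their mean level, less that of control, was 0.49 on silver nitrate replicate 2 and −0.06 and −0.21 on replicates 1 and 3.

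Glutathione S-transferases, which conjugate glutathione to electrophiles, rose with silver nitrate. Of 40 genes 30 lay higher, with a median of 0.19 (adjusted p = 3.01e-05, adjusted p = 0.215 with an estimated correlation). Over all probe sets 1 was called, gst-20 (1.49-fold, log2 difference 0.57 ± 0.08 SE, adjusted p = 0.0474), and 3 rose adjusted over the list alone. Targets of SKN-1, the regulator of phase II detoxification, rose as a group, with 20 of 25 lying higher and a median of 0.22 (adjusted p = 8.57e-05, adjusted p = 0.222 with an estimated correlation). This list shares 9 genes with the transferases, none passed over all probe sets and 4 rose adjusted over the list alone. Values were 0.98 for gst-30 (adjusted p = 0.101), 0.88 for gst-12 (adjusted p = 0.123) and 0.66 for sdz-8 (adjusted p = 0.176). ABC transporters rose as a group, with 32 of 48 lying higher and a median of 0.13 (adjusted p = 0.0127, adjusted p = 0.292 with an estimated correlation). None of the 48 passed by itself. The call ended without control replicate 2 (0.08, 0.131) or silver nitrate replicate 1 (0.04, 0.15), and its median was 0.09 without control replicate 1, 0.21 with the deposited scaling and 0.23 above median brightness. Without control replicate 3 the medians of the transferases and of the SKN-1 targets were each 0.09.

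Germline and DNA replication genes also rose with silver nitrate. Of 35 germline genes 28 lay higher, with a median of 0.31 (adjusted p = 3.01e-05, adjusted p = 0.222 with an estimated correlation), and gld-1, an RNA-binding regulator of meiosis, had a value of 1.04 (adjusted p = 0.214). The mean level of the list was 0.30 to 0.38 on the silver nitrate arrays and 0.28 on control replicate 1. Over lists restricted to probe sets above median brightness, chosen after the data were seen, the germline call ended (0.19, adjusted p = 0.0527). DNA replication genes rose as a group, with 23 of 30 lying higher and a median of 0.19 (adjusted p = 0.000302, adjusted p = 0.215 with an estimated correlation). None passed over all probe sets, 3 rose adjusted over the list alone, and rnr-1, a ribonucleotide reductase subunit, had a value of 0.48 (adjusted p = 0.08). Oocyte and eggshell genes rose as a group, with 21 of 30 lying higher and a median of 0.21 (adjusted p = 0.00167, adjusted p = 0.292 with an estimated correlation). Over all probe sets none passed and 2 rose adjusted over the list alone, with cpg-2 at 0.97 (adjusted p = 0.0584). The oocyte call ended without control replicate 2 (0.17, 0.0806), and its median was 0.14 without silver nitrate replicate 1 and 0.34 above median brightness. The DNA replication median was 0.11 without control replicate 3. Intestine markers rose with a median of 0.10 over 19 genes (adjusted p = 0.00819, adjusted p = 0.292 with an estimated correlation), a call that ended without silver nitrate replicate 1 (0.09, 0.114), with medians of 0.20 and 0.16 without control replicates 2 and 3, 0.19 after quantile normalisation and 0.18 with the deposited scaling.

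Neuropeptide genes fell as a group with silver nitrate, with 64 of 72 lying lower and a median of −0.21 (adjusted p = 1.73e-08, adjusted p = 0.292 with an estimated correlation). None passed over all probe sets and 4 fell adjusted over the list alone, and the median was −0.14 without control replicate 2, −0.13 after quantile normalisation and −0.14 with the deposited scaling. The value for ins-4 was −0.66 (adjusted p = 0.0702) and for flp-18 −0.63 (adjusted p = 0.103). Neuron markers did not pass (median −0.06, adjusted p = 0.157). Cytosolic heat shock genes fell as a group, with 17 of 22 lying lower and a median of −0.32 (adjusted p = 0.00923, adjusted p = 0.547 with an estimated correlation); none passed over all probe sets and 2 fell adjusted over the list alone. The small heat shock genes hsp-16.2 (−1.48, adjusted p = 0.154) and hsp-16.41 (−1.68, adjusted p = 0.157) and the chaperone hsp-70 (−1.15, adjusted p = 0.265) had the smallest p. The heat shock call ended without control replicate 1 (−0.24, 0.11) and after quantile normalisation (−0.20, 0.0751). Ribosomal protein genes fell as a group, with 74 of 75 lying lower and a median of −0.14 (adjusted p = 1.43e-05, adjusted p = 0.757 with an estimated correlation), and none passed over all probe sets or adjusted over the list alone. Their median was −0.08 without control replicate 2, −0.23 without silver nitrate replicate 1 and −0.02 without silver nitrate replicate 2 (adjusted p = 0.741), was −0.07 with the deposited scaling, and turned to 0.03 after quantile normalisation (adjusted p = 0.14).

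Limma called 30 probe sets between silver nitrate and control, 10 higher and 20 lower, and 2772 had an unadjusted p under 0.05. Genes that rose included C23H5.8 (4.73-fold, adjusted p = 0.0373, its other probe set at a log2 difference of 1.91 and adjusted p = 0.0729), hrg-11.2 (3.39-fold, adjusted p = 0.0474) and ife-5, a germline translation initiation factor (3.39-fold, control near the floor at 4.57, adjusted p = 0.0417). The DNA primase subunit pri-1 (1.96-fold, adjusted p = 0.0417) and the beta-catenin bar-1 (1.41-fold, adjusted p = 0.0454) rose too. Genes that were at the floor in control and rose were idpp-13 (at least 2.31-fold, adjusted p = 0.0266) and mab-3, a regulator of male development (at least 1.64-fold, adjusted p = 0.0454). The glucuronosyltransferase ugt-7 fell 2.28-fold (adjusted p = 0.0477) and the nuclear receptor nhr-89 fell at least 2.27-fold (adjusted p = 0.0474). The same lem-4 probe set was at least 2.25-fold lower (adjusted p = 0.00123). Of the 30, 13 carried a suffix that marks a match to several transcripts, and 8 had a group wholly at the floor. Of the 21 genes named by rule, ilys-3 kept its call whichever array was left out (adjusted p = 0.14 with the 6 compared arrays alone), and each of the other 20 lost it without at least 1 array (highest adjusted p = 0.132). The count was 46 and 19 without control replicates 1 and 2, then 16, 10 and 4 without silver nitrate replicates 1, 2 and 3. It was 13, 17 and 19 without aged replicates 1, 2 and 3 and 5, 12 and 7 without pristine replicates 1, 2 and 3. It was 185 above median brightness (75 higher, 110 lower), 53 without the dimmest 25%, 69 after quantile normalisation and 85 with a trend and robust fit. It was 11 with array weights, 9 with a floor of 1, 3 with a floor of 64 (0 higher) and 0 with the 6 compared arrays alone (limma, 2366 with an unadjusted p under 0.05). With the replicate number as a block it was 10, of which 6 were among the 30.

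**Figure D1:**
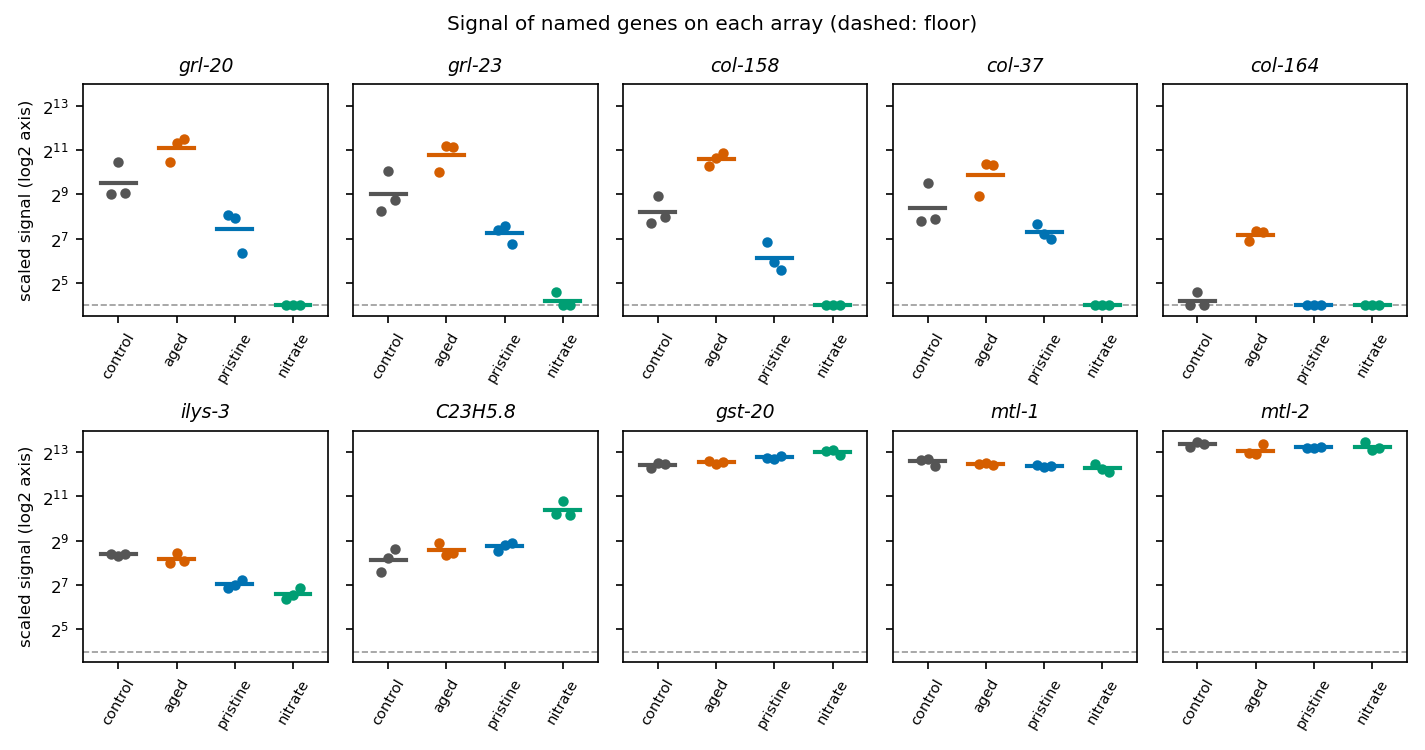
Scaled signal of 10 named genes on each of the 12 arrays (log2 axis), with dots for arrays, bars for the mean of a group on the log2 scale and a dashed line at the floor of 16. The probe sets that stand for grl-20, col-158 and col-37 sit at the floor in all 3 silver nitrate arrays, col-164 is over the floor in all 3 aged-particle arrays, and mtl-1 and mtl-2 lie near the top in every group.

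Metal-response and metal-transport genes did not pass as a group in any exposure. Over 21 genes the medians were 0.00 with aged particles, 0.08 with pristine particles and 0.08 with silver nitrate (adjusted p = 0.333, 0.624 and 0.595). The metallothioneins were among the brightest signals. Log2 differences of mtl-1 were −0.12, −0.21 and −0.31 with aged particles, pristine particles and silver nitrate, with a 95% interval of −0.53 to −0.08 for silver nitrate (adjusted p = 0.25). Those of mtl-2 were −0.29, −0.15 and −0.12, the last turning to 0.04 after quantile normalisation. The cadmium-responsive gene cdr-1 differed by −0.07, 0.13 and 0.22. A probe set that the annotation gives to numr-1 and another gene differed by 0.32, 1.95 and 0.80 with aged particles, pristine particles and silver nitrate (adjusted p = 0.752, 0.064 and 0.187). The pristine difference passed among the probe sets above median brightness (adjusted p = 0.00135). The probe set was lower with aged than with pristine particles (−1.63, adjusted p = 0.0496).

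Other stress genes named in advance did not pass against control either. The glutathione S-transferase gst-4 differed by 0.32, 0.83 and 0.32 with aged particles, pristine particles and silver nitrate (smallest adjusted p = 0.284). The superoxide dismutase sod-3 differed by 0.36, −0.59 and 0.45, and the endoplasmic reticulum chaperone hsp-4 by 0.20, 0.14 and 0.21. The yolk protein genes vit-2, near the floor in every group, and vit-6 differed by at most 0.21 in size. Of the 38 lists, 19 passed in no exposure, with medians from −0.18 to 0.18 and a smallest adjusted p of 0.11. They included C-type lectins (220 genes, medians −0.02 to 0.00), cytochrome P450s (73, 0.00 to 0.03), lipid metabolism (53, −0.02 to 0.02), the mitochondrial respiratory chain (35, −0.04 to 0.02), antioxidant enzymes (18, −0.09 to 0.13) and sulfide and hypoxia response (17, −0.17 to 0.15). A further set of list calls ended without 3 or more of the 12 arrays. With aged particles these were SKN-1 targets (median 0.10), germline (0.08), DNA replication (0.10) and ribosomal protein genes (−0.10). The germline median was 0.02 without control replicate 2, turned to −0.002 without control replicate 3, and was 0.22 and 0.15 without control replicate 1 and aged replicate 2. The SKN-1 median was 0.06 without control replicate 1. That of DNA replication was 0.16, 0.05 and 0.14 without control replicates 1 and 3 and aged replicate 2, and that of ribosomal protein genes −0.16, −0.05 and −0.06 without control replicates 1 and 2 and aged replicate 3. After quantile normalisation the ribosomal median was −0.02 and the call ended (adjusted p = 0.624), as did the calls of SKN-1 targets (0.12, 0.051) and germline genes (0.10, 0.0511). The germline call also ended above median brightness (adjusted p = 0.755) and with a gene's probe sets averaged (0.107). With pristine particles they were ABC transporters (0.08), DNA damage (0.12), DNA replication (0.16) and molting-cycle genes (−0.11). Without control replicate 2 the ABC median was 0.01 and the DNA damage median 0.05, and without pristine replicate 3 they were 0.04 and 0.07. The DNA damage median was 0.22 without pristine replicate 2, and that of DNA replication 0.07 without control replicate 3. After quantile normalisation the ABC, DNA damage and molting-cycle calls ended (adjusted p = 0.0727, 0.0919 and 0.0541), as they did with the deposited scaling (0.058, 0.058 and 0.0537). The ABC and DNA damage calls ended with a gene's probe sets averaged (0.0732 and 0.0848), and DNA damage above median brightness (0.326). The molting-cycle median was −0.07 with the deposited scaling and −0.17 above median brightness. With silver nitrate they were endoplasmic reticulum stress (0.17), pharynx (0.13) and vitellogenin genes (−0.41). The first had a median of 0.07 without control replicate 3 or silver nitrate replicate 2, and vitellogenins −0.17 without control replicate 3. The 5 vitellogenin genes had a mean log2 signal near the floor (5.31 in control), and their medians of −0.21 with aged and −0.42 with pristine particles did not pass (adjusted p = 0.127 and 0.111). The pharynx median was 0.22, 0.05 and 0.22 without control replicate 1 and silver nitrate replicates 1 and 3, and 0.20 with the deposited scaling. The endoplasmic reticulum call ended above median brightness (adjusted p = 0.136) and had a median of 0.11 with a gene's probe sets averaged, where the vitellogenin call ended (0.256). With an estimated correlation none of these calls held (adjusted p of 0.275 or more).

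**Figure D2:**
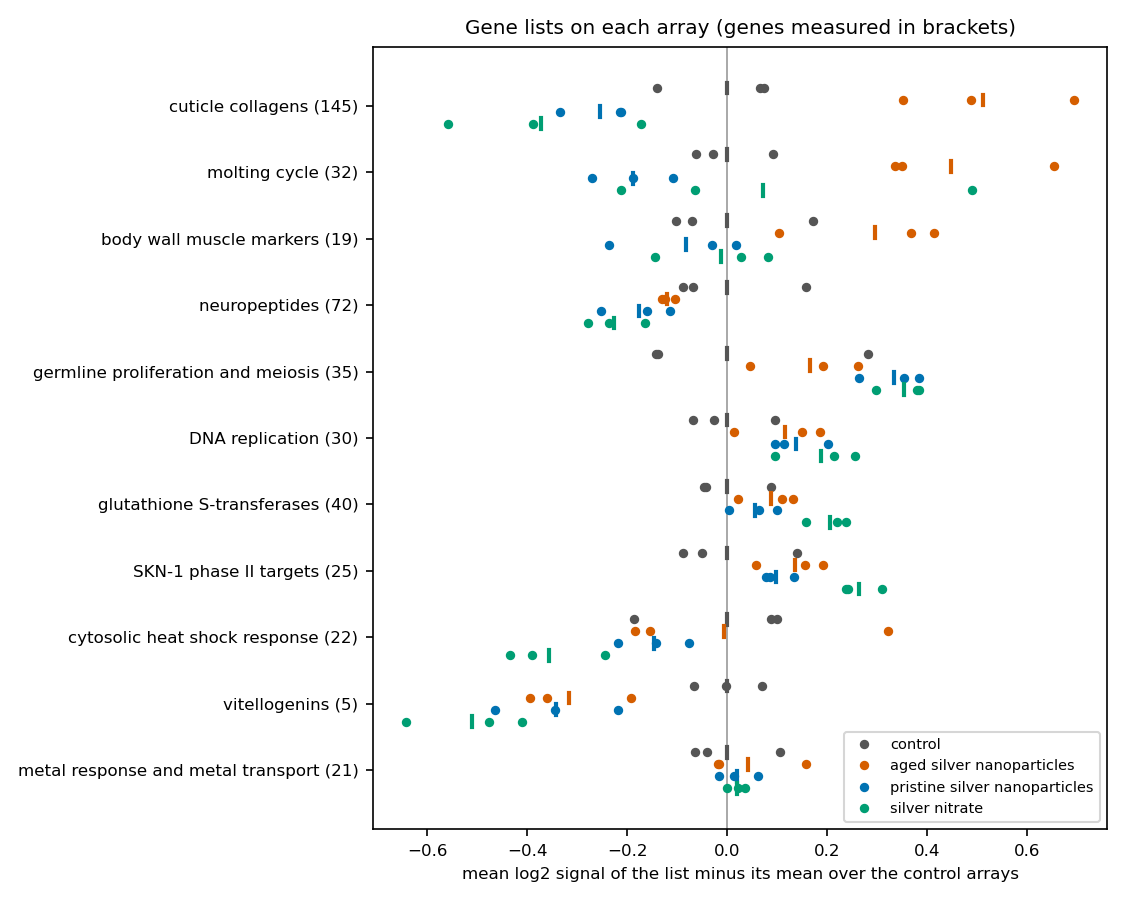
Mean log2 signal of 11 gene lists on each array, minus the mean of that list over the 3 control arrays, with dots for arrays and vertical bars for group means. Collagens lie over 0 in all 3 aged-particle arrays (0.35 to 0.69) and under 0 in all 3 silver nitrate arrays (−0.56 to −0.17), and the metal list lies near 0 in every group.

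The direct comparison of aged with pristine particles asked whether the response differed between the particle forms. Each form was given at its own concentration, so a difference cannot be assigned to sulfidation alone. Cuticle collagens were higher with aged particles, with a median log2 difference of 0.51 over 145 genes (adjusted p = 1.77e-24, adjusted p = 0.0249 with an estimated correlation). Of these, 9 were higher over all probe sets and 45 adjusted over the list alone. The collagens col-158 and col-114 were 22.1-fold and 20.9-fold higher (adjusted p = 0.00623 and 0.00173), and col-45 was at least 16.1-fold higher, with all pristine arrays at the floor (adjusted p = 0.0496). The cuticle gene cut-1 was 10.1-fold higher, col-35, with 1 pristine array at the floor, at least 11.1-fold and grl-23 11.6-fold (adjusted p = 0.0496 each). On pristine arrays col-114 and cut-1 lay close to the floor of 4 (means of 4.41 and 4.39), so these 2 folds are against a level little above background. Molting-cycle genes were higher (median 0.47, adjusted p = 1.51e-07, adjusted p = 0.177 with an estimated correlation), 1 over all probe sets and 9 adjusted over the list alone. Body wall muscle markers were higher too (0.40, adjusted p = 1.6e-07, adjusted p = 0.425 with an estimated correlation), 9 of them adjusted over the list alone.

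Lysozymes and antimicrobial effectors were higher with aged than with pristine particles (median 0.12, adjusted p = 0.000449, adjusted p = 0.297 with an estimated correlation), 2 of them over all probe sets, and the median was 0.04 without aged replicate 2. Among these ilys-3 differed by 1.14 (adjusted p = 0.0496), and the C-type lectin clec-60, outside that list, by 1.31 (adjusted p = 0.0496). Sulfide and hypoxia response genes, 17 measured, had a median of 0.23 (adjusted p = 0.0139, adjusted p = 0.803 with an estimated correlation). That call ended without aged replicate 2 (0.10, 0.208) or pristine replicate 1 (0.22, 0.1), and the median was 0.37 above median brightness. Lower with aged particles were sst-20, at the floor in 2 of 3 aged-particle arrays and so by at least 4.02-fold (adjusted p = 0.0469), and M01E5.1, by at least 2.09-fold (adjusted p = 0.0496). Ribosomal protein genes were lower (−0.09, adjusted p = 0.00105, adjusted p = 0.803 with an estimated correlation), a call that ended without aged replicate 3 (−0.05, 0.0795) and after quantile normalisation (−0.03, 0.162).

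Between the particle forms 25 probe sets differed, 22 higher and 3 lower with aged particles, 107 did above median brightness (93 higher, 14 lower), and 8 did with the 6 compared arrays alone. With the replicate number as a block 14 did, 9 of them among the 25. Of the 25, 5 carried a suffix that marks a match to several transcripts, and 5 had a group wholly at the floor. The 3 genes col-164, col-114 and col-158 kept their calls whichever array was left out, of which col-158 lost its call with the 6 compared arrays alone (adjusted p = 0.101), and the other 10 genes named by rule lost theirs without at least 1 (highest adjusted p = 0.163). The count was 9 and 5 without control replicates 1 and 3, 7 and 6 without aged replicates 2 and 3, and 12, 7 and 5 without pristine replicates 1, 2 and 3. It was 8, 12 and 11 without silver nitrate replicates 1, 2 and 3.

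Between aged particles and silver nitrate, collagens as a group and the ground-like genes grl-20 and grl-23 were higher with aged particles. The gene grl-20 was at least 136-fold higher by the probe set that stands for it (adjusted p = 0.00147) and 38.9-fold by the other (adjusted p = 0.00734). The collagen col-158 was at least 96.3-fold higher (adjusted p = 0.000329), grl-23, at the floor in 2 of 3 silver nitrate arrays, at least 95.4-fold (adjusted p = 0.00147), col-37 at least 58.0-fold (adjusted p = 0.00338) and col-2 53.7-fold (adjusted p = 0.01). Collagens as a group had a median of 0.55 (adjusted p = 2.68e-25, adjusted p = 0.0224 with an estimated correlation). Of 145, 16 were higher over all probe sets, and 50 were higher and 1 lower adjusted over the list alone. Lower with aged particles were ZK228.3 (at least 3.62-fold, 1 aged-particle array at the floor, adjusted p = 0.0153), C23H5.8 (3.55-fold, adjusted p = 0.0459, its other probe set at −1.55 and adjusted p = 0.121), the glucuronosyltransferase ugt-9 (2.34-fold, adjusted p = 0.0153) and mab-3 (at least 1.63-fold, 2 aged-particle arrays at the floor, adjusted p = 0.0233).

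Muscle markers were higher with aged particles than with silver nitrate (median 0.30, adjusted p = 3.9e-06, adjusted p = 0.609 with an estimated correlation), as were lysozymes and antimicrobial effectors (0.13, adjusted p = 0.00213, adjusted p = 0.609 with an estimated correlation; 0.06 without aged replicate 2, 0.08 after quantile normalisation). Molting-cycle genes were higher (0.20, adjusted p = 0.0026, adjusted p = 0.609 with an estimated correlation), a call that ended without aged replicate 2 (0.16, 0.0689) or silver nitrate replicate 3 (0.23, 0.0514), with medians of 0.35 without aged replicate 3, 0.37 without silver nitrate replicate 2 and 0.31 with a gene's probe sets averaged. Heat shock genes were higher (0.22, adjusted p = 0.00397, adjusted p = 0.637 with an estimated correlation), a call that ended without aged replicate 2 (0.11, 0.0689). That array had the highest heat shock level of the 12. The heat shock median was 0.14 and 0.34 without silver nitrate replicates 2 and 3. Glutathione S-transferases were lower with aged particles (−0.11, adjusted p = 0.0264, adjusted p = 0.634 with an estimated correlation), a call that ended without aged replicate 3 (0.164) or silver nitrate replicate 2 (0.146). Neuropeptide genes were higher (0.09, adjusted p = 0.00574, adjusted p = 0.738 with an estimated correlation), a call that ended without silver nitrate replicate 2 (0.05, 0.0674) and after quantile normalisation (0.04, 0.18). The median was 0.055 without aged replicate 2 and 0.05 with the deposited scaling. Oocyte (−0.18), germline (−0.15) and intestine (−0.09) genes were lower (adjusted p = 0.0409, 0.0409 and 0.0374, adjusted p = 0.637 each with an estimated correlation), and each of these calls ended without 4 or more of the 12 arrays. The intestine median was −0.18, −0.15 and −0.19 without aged replicate 1 and silver nitrate replicates 2 and 3, and −0.17 after quantile normalisation. The oocyte and germline calls ended after quantile normalisation (adjusted p = 0.0547 each) and with the deposited scaling (0.0768 and 0.0754). All 3 ended above median brightness (0.0528, 0.113 and 0.0654, oocyte median −0.27) and with a gene's probe sets averaged (0.0593, 0.124 and 0.116).

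Limma called 57 probe sets between aged particles and silver nitrate, 47 higher and 10 lower with aged particles, 182 above median brightness (147 higher, 35 lower) and 13 with the 6 compared arrays alone. With the replicate number as a block it called 37, 31 of them among the 57. Of the 57, 18 carried a suffix that marks a match to several transcripts, both grl-20 probe sets among them. A group lay wholly at the floor for 12 of the 57. Of 21 genes named by rule, 9 kept their calls whichever array was left out and 12 lost theirs without at least 1 (highest adjusted p = 0.169). Of the 9, col-2, col-37, col-84 and ilys-3 lost theirs with the 6 compared arrays alone (adjusted p = 0.0837, 0.0644, 0.0945 and 0.163). The count was 24 and 25 without aged replicates 2 and 3, 24 and 30 without silver nitrate replicates 1 and 3, and 36 without pristine replicate 2.

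**Figure D3:**
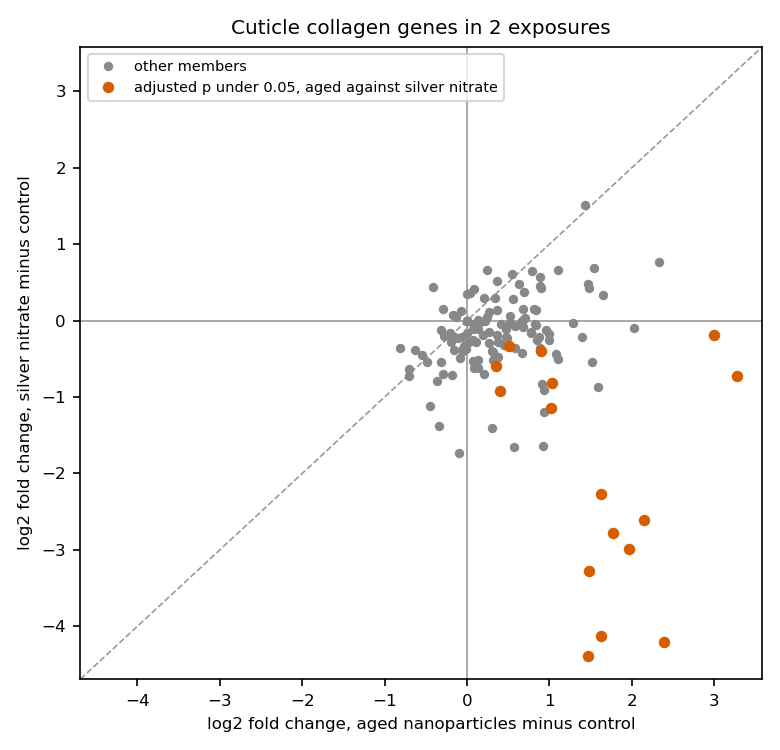
Log2 difference from control of each of the 145 collagen genes with aged particles (horizontal) and silver nitrate (vertical), with orange for the 16 that differed between these exposures and a dashed line of equal change. The 16 were all called higher with aged particles than with silver nitrate, so they lie under the dashed line by definition.

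Pristine particles and silver nitrate differed in glutathione S-transferases, which were lower with pristine particles over 40 genes (median −0.15, adjusted p = 0.00312, adjusted p = 0.78 with an estimated correlation). That call ended without pristine replicate 3 (−0.13, 0.0508) or silver nitrate replicate 2 (−0.11, 0.0513). Ribosomal protein genes were higher with pristine particles (0.15, adjusted p = 1.02e-07, adjusted p = 0.797 with an estimated correlation). Their median was 0.23 without silver nitrate replicate 1, 0.02 without silver nitrate replicate 2 (adjusted p = 0.506) and −0.00 after quantile normalisation (adjusted p = 0.831). Targets of SKN-1 (−0.17), antioxidant enzymes (−0.16) and intestine markers (−0.08) were lower with pristine particles (adjusted p = 0.0449, 0.0362 and 0.0449, adjusted p = 0.78 each with an estimated correlation), and each of these calls ended without 4 or more of the 12 arrays. Without silver nitrate replicate 2 the SKN-1 and antioxidant medians were −0.09 and −0.11. The intestine median was −0.14, −0.03 and −0.15 without pristine replicate 1 and silver nitrate replicates 1 and 3, −0.14 after quantile normalisation and −0.12 with the deposited scaling. The SKN-1 call ended after quantile normalisation (adjusted p = 0.0529) and with the deposited scaling (0.0655), the SKN-1 and intestine calls above median brightness (0.0593 each) and the intestine call with a gene's probe sets averaged (0.0785). Collagens did not pass between these exposures (adjusted p = 0.335). The 1 probe set called by limma belongs to pqn-41, which codes for a glutamine-rich protein and was chosen after its values were seen. It was at the floor in all pristine arrays, so at least 2.42-fold lower than with silver nitrate (adjusted p = 0.0433, and 0.0886 with the 6 compared arrays alone), and the brightest of the 4 pqn-41 probe sets differed the other way (0.64, adjusted p = 0.386). Genes with the smallest p did not pass. They were Y49G5B.1 (−0.59, adjusted p = 0.157, its other probe set the other way at 0.61 and adjusted p = 0.766), nas-39 (0.98), C40H1.7 (−2.09, 1 pristine array at the floor), M01E5.1 (0.93, 2 silver nitrate arrays at the floor) and srsx-18 (1.52, silver nitrate at the floor), the last 4 with an adjusted p of 0.161 each. An unadjusted p under 0.05 was reached by 2152 probe sets, and 80 were called above median brightness (47 higher, 33 lower) and 0 after quantile normalisation (limma, 2205 with an unadjusted p under 0.05). The count was 0 without control replicate 1, aged replicate 2 or 3, or pristine replicate 3 (limma, 1538 to 2146 with an unadjusted p under 0.05), and 4 and 3 without control replicates 2 and 3. It was 12 and 13 without pristine replicates 1 and 2, and 3 and 4 without silver nitrate replicates 1 and 2. The pqn-41 call ended in 8 of the 12 leave-one-out fits, those with a count of 0 and those without aged replicate 1 or any silver nitrate replicate, where the probe sets called were others. It also ended with a trend and robust fit, a floor of 1 or 64 and after quantile normalisation or centring.

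Over all 4 groups, 14 probe sets differed by the F test, 2902 had an unadjusted p under 0.05, and 224 differed above median brightness. The F count was 27, 43 and 24 without control replicates 1, 2 and 3, and 32 and 25 without pristine replicates 1 and 2. The lem-4 probe set was the 1 probe set changed in all 3 exposures, lower each time, and none of these 3 calls held with the 6 compared arrays alone or with a floor of 1 or 64. With a trend and robust fit the aged-particle and pristine-particle calls ended (adjusted p = 0.0649 and 0.0532) and the silver nitrate call held (0.0171). Each exposure was compared with the same 3 control arrays, and simulated unchanged exposures shared a mean of 0.05 to 0.09 calls per pair over 100 simulations. Across probe sets, log2 changes with pristine particles and with silver nitrate correlated at r = 0.536, against 0.498 for simulated unchanged exposures that share the controls. The values for aged and pristine particles (0.356) and for aged particles and silver nitrate (0.399) lay under the simulated 0.5. Covariances of the log2 changes were 0.0633, 0.0395 and 0.0488 in the same order, against a simulated 0.0388 to 0.0389 (SD 9e-04). The simulated probe sets varied independently, so this SD leaves out genes that move together and cannot test the differences. Probe sets are not independent replicates, and the 3 controls cannot be divided between exposures.

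The 3-prime minus 5-prime signal of the array control genes actin, Gapdh and ubiquitin averaged 2.01 ± 0.09 in control, 1.97 ± 0.08 with aged particles, 1.99 ± 0.07 with pristine particles and 1.85 ± 0.15 with silver nitrate (log2, SD, n = 3). The silver nitrate difference of −0.16 gave an exact permutation p of 0.2 (two-sided), where the smallest this design allows is 0.1. Silver nitrate replicate 2 had a value of 1.68, under the 1.92 to 2.10 of the other 11 arrays, and without it the difference was −0.07. Of the 53 list calls, 14 ended without that array, and 5 to 12 without each of the others.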

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

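The test of RNA integrity and the counts of splits for single lists, other than that of the collagen difference between aged particles and silver nitrate, were chosen after the results were seen. Cuticle collagens differed between the particle forms, with medians on opposite sides of 0, at 0.36 for aged and −0.19 for pristine particles against control and a difference of 0.51 (camera adjusted p = 1.77e-24, adjusted p = 0.0249 with an estimated correlation). They also differed between aged particles and silver nitrate, at 0.36 and −0.21, a difference of 0.55 (adjusted p = 2.68e-25, adjusted p = 0.0224 with an estimated correlation). Molting-cycle genes differed between the particle forms, at 0.33 and −0.11, a difference of 0.47 (adjusted p = 1.51e-07, adjusted p = 0.177 with an estimated correlation). Among 100 random splits of the 12 arrays, the real one included, 7, 37 and 39 gave a collagen median against control as far from 0 as those of aged particles, pristine particles and silver nitrate (real sizes 0.364, 0.19 and 0.206, highest other 0.468, 0.578 and 0.449), so chance is not excluded for these medians against control. For molting-cycle genes with pristine particles 64 did (0.107, highest other 0.441), so chance is not excluded there either. For molting-cycle genes with aged particles 4 did (0.333, highest other 0.386), but counted over any of the 6 contrasts 24 did (highest other 0.506), so chance is not excluded for it. Over any of the 6, for the differences between the particle forms, 2 did for molting-cycle genes (0.469, highest other 0.506) and 4 for collagens (0.514, highest other 0.578), both under 5 of 100.

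For the collagen difference between aged particles and silver nitrate, the values argue against scaling as its source, since it was 0.541 after quantile normalisation, and against a single array, since leaving out any 1 array left at least 0.424. With the 3-prime minus 5-prime signal as a covariate it was 0.649, which argues against RNA integrity as its whole source. The 12 arrays were also split at random into 4 groups of 3, giving 100 splits with the real one included. Of these, 3 gave a collagen median as far from 0 in any contrast (real 0.553, highest other 0.578). Chance is thus unlikely to give a difference of that size between exposures. It is not excluded, since other splits gave more and the count does not allow for the choice of this list among all lists. A candidate explanation is that animals were at different points of the molting cycle when RNA was taken. Differences among replicates of a group lay weakly along the same direction. The cosine between the first residual component and the difference was 0.273, just over the 95th percentile of 0.266 for 1000 random gene sets. Random sets need not vary together as a gene family can, so this alignment cannot single out molting stage. A difference in molting stage stays open as a hypothesis, since collagens and molting genes turn over with each molt. Whether silver altered growth rate or the cuticle itself was not tested.

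Other splits of the arrays were also counted for the numbers of changed probe sets. The F test called 14 probe sets, and 2 of 100 splits gave as many, the real one included (highest other 15). The 6 contrasts together called 53 lists, and 2 of 100 splits gave as many (highest other 55), while a random split called a median of 30. Both counts are under the 5 of 100 set in advance, so chance is unlikely to give these numbers. It is not excluded, since another split gave more each time and the splits treat arrays as independent, which the labels do not settle. Taken singly and counted over any of the 6 contrasts, 47 of the 53 medians were matched in size by 5 or more of 100 splits, so chance is not excluded for these. In the same contrast 36 were, by 5 to 64 splits. These include lysozymes and antimicrobial effectors with aged particles (37 splits, real 0.084, highest other 0.171), neuropeptides with aged particles (22, 0.133 and 0.216), ribosomal protein genes with silver nitrate (31, 0.138 and 0.23) and oocyte genes with silver nitrate (15, 0.207 and 0.303). With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For aged particles against control 2 of the 10 gave as many probe sets (real 2, highest other 7), for pristine particles 8 (1 and 4), for silver nitrate 1 (30 and 3), for aged against pristine particles 1 (25 and 3), for aged particles against silver nitrate 1 (57 and 2) and for pristine particles against silver nitrate 3 (1 and 4).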

How the results depend on the processing

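The results with the deposited scaling, and gene lists over probe sets above median brightness, were chosen after the data were seen. Under centring on array medians and the replicate block all 53 list calls kept their direction and side of the threshold. Every group holds the same replicate numbers, so the block leaves every list median unchanged by construction. Centring is the main median scaling with the floor set before it. Neither setting is thus a strong check on direction. After quantile normalisation 39 list calls kept both, 12 ended and 2 turned: ribosomal protein genes with silver nitrate to 0.027 (adjusted p = 0.14) and with pristine particles against silver nitrate to −0.001 (adjusted p = 0.831). The deposited scaling ended 6, averaging a gene's probe sets 8 and the brightness filter 9, with no turn, and that filter gave no value for vitellogenins with silver nitrate. Counts under a 1.5-fold threshold stayed within 1.5 times of the value with none in all 7 limma results, and no named gene turned in direction past its test. Estimating the correlation left 2 list calls and 4 class calls, and fry called 9 lists. For each changed count below, the cause was not tested, except that fits with the 6 compared arrays alone have fewer degrees of freedom and a stricter threshold calls fewer by construction. The 6-array fits also drop the other groups, whose floored arrays lower the pooled spread of some probe sets. Signal over background limits these arrays: values under the floor carry no difference, and folds against it are lower bounds.

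In the order aged, pristine and silver nitrate against control, quantile normalisation gave 4, 19 and 69 changed probe sets, the filter on the dimmest 25% gave 0 (limma, 1416 with an unadjusted p under 0.05), 3 and 53, and the filter below median brightness 13, 13 and 185. The trend and robust fit gave 1, 5 and 85, a floor of 1 gave 4, 2 and 9, and a floor of 64 gave 9, 2 and 3. With the 6 compared arrays alone the counts were 1, 0 (1782 unadjusted) and 0 (2366 unadjusted). Centring gave 4 and the deposited scaling 6 for pristine particles, array weights 11 for silver nitrate, and an adjusted p under 0.01 gave 1 for silver nitrate.

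For aged against pristine particles the counts were 43 (quantile), 40 (centring), 48 and 107 (dimmest 25% and below the median left out), 95 (trend), 50 (weights), 11 (floor 1), 42 (deposited scaling), 8 (6 arrays) and 3 (adjusted p under 0.01). For aged particles against silver nitrate they were 182 (below the median left out), 118 (trend), 13 (6 arrays) and 13 (adjusted p under 0.01). For pristine particles against silver nitrate limma gave 0 with quantile normalisation (2205 unadjusted), centring (2002), the filter on the dimmest 25% (1674), the trend (2077), a floor of 64 (1707) and an adjusted p under 0.01, then 3 with a floor of 1 and 80 with the filter below the median. The F test gave 62 (quantile), 58 (centring), 61 and 224 (filters), 114 (trend), 47 (weights), 22 and 23 (floors of 1 and 64) and 66 (deposited scaling). Probe sets shared by at least 2 exposures numbered 8 after quantile normalisation, against 1.

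Replicate numbers were not taken to pair the arrays, since nothing in the labels says that equal numbers share a culture, day or batch. The residuals hint at pairing among exposed arrays, where all 9 pairs of equal number had a positive r (0.023 to 0.217, median 0.151). The 9 pairs with a control array had r of −0.244 to 0.079 (median −0.053), and pairs of unequal number a median of −0.014. Of the 18 pairs of equal number 5 had r over 0.1, all of them between exposed arrays. Of 12 arrays, 7 correlated best with an array of their own number, a hint from the data and not the design. Some arrays would do so by chance. The residuals of a group sum to 0, so the pairs are not independent. Positive values at equal numbers thus lower those at unequal numbers. With the numbers as a block the counts were 7, 1 and 10 against control, 14 for aged against pristine particles, 37 for aged particles against silver nitrate, 0 for pristine particles against silver nitrate (2273 unadjusted), 26 for F and 55 lists. Without 1 array in turn, the counts ranged from 2 to 16 (aged), 1 to 17 (pristine) and 4 to 46 (silver nitrate) against control, 5 to 23 for aged against pristine particles, 24 to 67 for aged particles against silver nitrate, 0 to 13 for pristine particles against silver nitrate, 12 to 43 for F and 41 to 55 for lists. The 2 remaining arrays of a group were then assumed to vary like the other groups.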

Other observations

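The test of the neuron marker share was chosen after the result was seen, as were the condition that genes set beside the ribosomal ones be as bright and the genes given first, which come from the fit over the 11274 probe sets above median brightness. In that fit, the acyl-CoA synthetase acs-2 was lower with silver nitrate than with pristine particles by 2.86 on the log2 scale (limma adjusted p = 0.034, its other probe set 2.15 and not called), the transcription factor mxl-3 by 1.85 (adjusted p = 0.0455), the aquaporin aqp-1 by 1.40 (adjusted p = 0.0207) and the flavin monooxygenase fmo-2 by 1.29 (adjusted p = 0.0309). Of the 80 probe sets called there 33 went the other way, with pristine minus silver nitrate values of −1.64 for C23H5.8 (adjusted p = 0.0144, its other probe set −1.42 and 0.034), −1.11 for gst-30 (adjusted p = 0.0203) and −1.03 for sod-3 (adjusted p = 0.0492). Over all probe sets the limma adjusted p was 0.174 for C23H5.8 and 0.241 for sod-3. Against control, silver nitrate gave −2.16 for the sugar transporter swt-1 (adjusted p = 0.0027), −0.78 for the triglyceride lipase atgl-1 (adjusted p = 0.0191, and 0.077 over all probe sets, its other probe sets −0.86 and −0.42 and not called) and −0.71 to −0.82 for 3 probe sets of sams-1, which makes S-adenosylmethionine (highest adjusted p = 0.0391). In the same fit hsp-16.2 and hsp-16.41 passed, at −1.48 (adjusted p = 0.0339) and −1.68 (adjusted p = 0.0342). Higher with silver nitrate than in control were acdh-1, which codes for an acyl-CoA dehydrogenase (2.96, adjusted p = 0.000921), ttr-22 (1.85, adjusted p = 0.022) and bcf-1 (1.80, adjusted p = 0.00864). With pristine particles ilys-3 (−1.35, adjusted p = 0.00328) and ins-4 (−0.76, adjusted p = 0.0486) were lower than in control. None of the genes given from this fit passed over all probe sets in the same contrast. Random splits of the arrays were not counted in this fit, so chance was not checked for these genes.

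Gene classes, taken from the letters of the symbols, were tested beside the lists. With aged particles against control 12 classes were called higher and 5 lower. The lower ones were mrpl (median −0.14), flp (−0.13), gcy (−0.27), rps (−0.10) and glb (−0.18), with adjusted p from 0.00199 to 0.0431 and of 0.502 or more with an estimated correlation. Of the higher ones, 3 were chosen after their values were seen. The ground-like class grl, 30 genes, had a median of 0.61 (camera adjusted p = 9.66e-06, adjusted p = 0.15 with an estimated correlation), the groundhog class grd 0.41 over 12 genes (adjusted p = 4.4e-05, adjusted p = 0.23 with an estimated correlation) and the class abu 1.11 over 11 genes (adjusted p = 2.73e-07, adjusted p = 0.28 with an estimated correlation). The grl class had a median of −0.26 with pristine particles (adjusted p = 0.0131, adjusted p = 0.529 with an estimated correlation) and −0.31 with silver nitrate (adjusted p = 0.0298, adjusted p = 0.704 with an estimated correlation). With an estimated correlation 4 class calls held, col and grl with aged against pristine particles (adjusted p = 0.0227 each) and with aged particles against silver nitrate (adjusted p = 0.0285 and 0.0361). The 6 contrasts called 78 classes in all, and 7 of 100 random splits gave as many, the real one included (highest other 98), so chance is not excluded for that number.

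Ribosomal protein genes had a median of −0.138 with silver nitrate, a size that may be technical. The 65 nearest genes in brightness that are not ribosomal had a median of −0.189, so the fall was not particular to ribosomal protein genes. With aged and pristine particles these 65 had medians of −0.111 and −0.012, against −0.101 and 0.009 for ribosomal protein genes. They were dimmer (mean log2 signal 13.31 against 14.36), so they do not test compression of bright signals, which stays open. Without silver nitrate replicate 2 the ribosomal median was −0.016, so 1 array carries most of it, and no biological explanation was tested.

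Neuropeptide genes were lower in all 3 exposures, and the shared control arrays could give such a pattern. Without control replicate 2 the medians were −0.035, −0.057 and −0.137 with aged particles, pristine particles and silver nitrate, against −0.133, −0.169 and −0.213 with all arrays, so the smallest remaining share was 0.263. A smaller share of neural tissue in exposed animals would lower neuron markers as well. The ratio of the neuron marker median to the neuropeptide median was 0.714, 0.083 and 0.3 in the same order, and the marker list passed in no exposure (smallest adjusted p = 0.157). A smaller neural share and a change in the neuropeptide genes themselves cannot be told apart, since the members of the marker list went both ways and the neuropeptide medians depend on 1 control array.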
